A study of Ovis aries with 22 samples.

How the data were processed

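RNA sequencing was done on wall tissue of the arterial sinuses of sheep (Ovis aries). The Ross procedure moves a patient's own pulmonary root into the aortic position, and the transplanted root is called the pulmonary autograft. Autograft sinus was taken from 3 operated animals 6 months after surgery, and native aortic sinus and native pulmonary sinus were taken from 4 other animals, named D3 to D6 in the labels. The 22 sample entries are 11 libraries, each sequenced in 2 runs under the same index pair. The replicates of a group are separate animals per the labels. In the labels, aortic sinus replicate 1 (animal D3) carries the treatment "Ross surgery", while the design text places native tissue in non-operated sheep. That library stayed in the aortic group, and each comparison was also run without it and without animal D3.

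RNA was extracted with TRIzol and libraries were made with a TruSeq kit, per the labels' protocols. The submitters' processing notes name cutadapt, Bowtie2 2.3.3.1, STAR 2.5.2b and featureCounts 1.5.3 with no role or order. The genome build, the gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes, antisense genes and near-identical copies cannot be separated further. The deposited count tables, 1 per run, hold raw whole-number counts for 26200 gene symbols. A row without a gene name held at most 0.000602% of a library's counts and stayed out of library sizes and tests. The deposited FPKM tables, 1 per run, hold the authors' FPKM for 15272 genes in run 1 and 15080 in run 2. The step from counts to FPKM is not given in the sources used here. In those tables the values of a gene are whole multiples of 1 step, the multiples have the same quantiles in every library, and no value is 0, even where the raw count is 0 (4505 values in run 1). Their distribution was therefore made equal between libraries before deposit. The FPKM values served only as an alternative unit. Sheep gene names of NCBI RefSeq, assembly ARS-UI_Ramb_v3.0, matched 18733 of the 26200 symbols. That table was used for names and gene types only, and no coordinates are given.

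Counts of the 2 runs were added per library. Runs of the same library differed by a chi-square of 1.39 to 1.52 per gene, against 22.0 to 76.1 between libraries of the same group, so the runs were counted as 1 sample. Summed totals lay between 17380599 and 20741334 counts per library, from 5366411 to 6554596 in run 1 and from 11882812 to 14186738 in run 2. At this depth a library held counts for 17006 to 17940 genes, and the 10 most abundant genes took 8.26% to 13.9% of the counts.

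All settings in this paragraph were fixed before the data were examined, and so were the gene lists, the rule for naming genes and the alternatives, unless said otherwise. Genes were filtered with edgeR's filterByExpr by group, which left 14979 genes. Libraries were scaled by TMM, and all 3 groups entered 1 edgeR quasi-likelihood fit without a block (R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0). A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 over all genes tested. Log2 fold changes carry standard errors (SE) from that fit, and expression is given as CPM with the TMM scaling, as mean ± SD over animals. CPM values of single libraries on a log2 scale have a prior count of 2. Of 38 gene lists, 37 had at least 5 genes tested and were tested against the other genes by camera with a preset correlation of 0.01 between genes. An estimated correlation and the self-contained test fry were run beside it. For each list, counts of called members are given over all genes and adjusted over the list alone. Per comparison, the named genes were the 8 largest rises and the 8 largest falls among called genes. These had an absolute log2 fold change of at least 1, no overlap between the libraries of the 2 groups, a mean of at least 5 CPM in the higher group and a gene symbol. In addition came the members of each list with the smallest p, up to 4 for a called list and up to 2 otherwise. The result of 1 gene that this rule names is not reported here.

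The overlap of the calls in 2 comparisons that share libraries was set beside simulated unchanged groups and beside the number that independent lists would share. A position score placed each library between pulmonary sinus (0) and aortic sinus (1). For each of the 6 choices of 2 native animals, the 500 genes that differed most between the sinuses in those animals were signed and averaged, and the scale was set in the other animals. Autograft scores were compared with native scores by two-sided exact permutation tests, whose smallest possible p is 0.0286 for 3 against 4 libraries.

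The native libraries are paired by the animal named in the labels. The correlation of deviations from the group means was -0.18 for D3, -0.13 for D4, 0.43 for D5 and 0.45 for D6, while the aortic library of D4 and the pulmonary library of D3 gave 0.40 and the reverse pair 0.26. The autograft libraries share only a replicate number with the native ones. As an alternative a fixed block was run, by animal in the native comparison and by replicate number in those of the autograft. The random block was by animal, in limma-voom with all 3 groups.

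Alternatives were DESeq2's size factors, total counts without TMM, no low-count filter, DESeq2, limma-voom, a fit of only the 2 groups compared, each run alone, the replicate block as a fixed and as a random effect, a fold threshold, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), only genes with a mean FPKM of at least 1, the mean of the cardiomyocyte list as a covariate, each library left out in turn, and both D3 libraries left out. Chosen after the data were seen were a block with D3 and D4 crossed between the tissues, and a fit without pulmonary sinus replicate 1 and autograft sinus replicate 1, which stood apart from their groups on the first principal components.

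The scripts were tested on simulated data, with 1 simulation per comparison in which 67, 67 and 66 genes were changed by 1.5-fold, 2-fold and 4-fold among 14639, 14638 and 14611 genes, in the order of the comparisons below. For autograft against pulmonary sinus, 10.4% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 97.0% of those changed 4-fold were recovered, and 1.85% of calls were false. For autograft against aortic sinus these shares were 7.46%, 46.3% and 90.9%, with 5.88% false. For aortic against pulmonary sinus they were 14.9%, 64.2% and 95.5%, with 3.33% false. A list changed 2-fold was called in each simulation, and a position planted midway came back at 50.0% of the scale. Figures were drawn with matplotlib 3.10.9. A list of blood cell markers had 2 genes tested and was left out. A check of gene length or GC content was not run, because the build and annotation behind the counts are not given in the sources used here.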

Results

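Gene expression was measured by RNA sequencing in the sinus wall of sheep great arteries. The groups were pulmonary autograft sinus from 3 animals, sampled 6 months after the Ross procedure, and aortic sinus and pulmonary sinus from 4 non-operated animals. In the autograft the pulmonary root had been carried by the aortic position, so each native sinus answers a different question. Pulmonary sinus is the tissue the autograft was made from, and aortic sinus is the tissue native to the place it was moved to. Library totals lay between 17380599 and 20741334 counts and did not separate the groups. On the first principal component, which held 37.9% of the variance, the autograft libraries lay at 63.1, 72.8 and 37.2 and the aortic libraries between -30.6 and 8.46. Pulmonary replicates 2 to 4 lay between -67.6 and -29.5, and pulmonary replicate 1 lay at 9.34, beside the aortic libraries. Autograft replicate 1 stood apart from the other libraries on the second component, at 64.1.

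**Figure D1:**
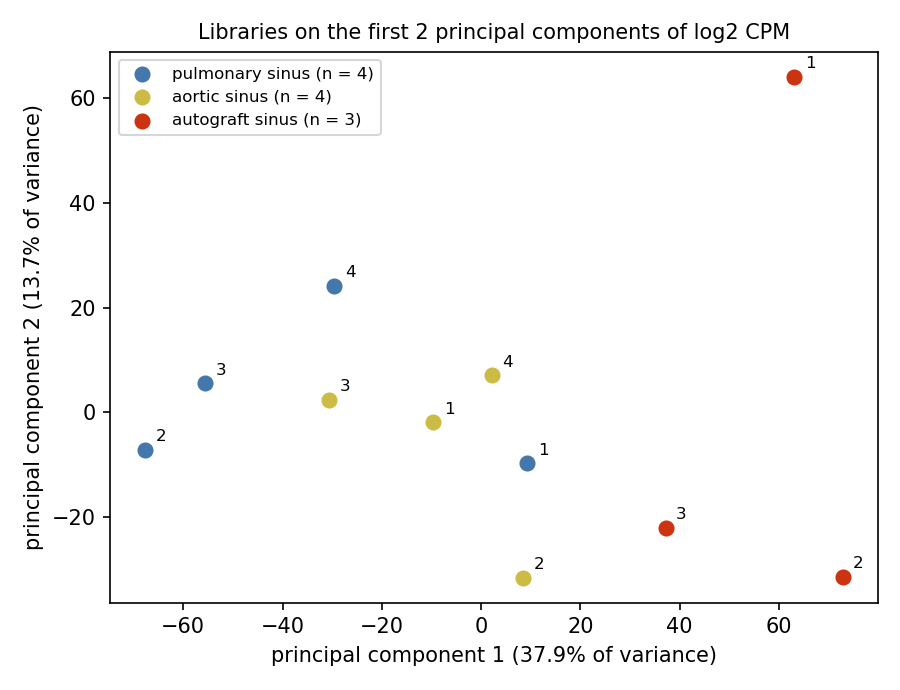
Principal components of log2 CPM for the 11 libraries, with the percent of variance on each axis and the replicate number beside each point. The 3 autograft libraries lie between 37.2 and 72.8 on the first component, and pulmonary replicate 1 (9.34) lies apart from the other pulmonary libraries.

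The first comparison asked how the autograft differed from native pulmonary sinus, the kind of tissue it was made from, taken from other animals. IL2RB, CD3E, MGP and COL1A1 were higher in the autograft, and MYOCD and CACNA1C were lower. IL2RB, a subunit of the interleukin-2 receptor of lymphocytes, rose from 0.380 ± 0.169 CPM (SD, n = 4) to 10.6 ± 3.65 CPM (SD, n = 3), a log2 fold change of 4.78 ± 0.44 (SE). MYOCD, which encodes myocardin, a coactivator of smooth muscle gene transcription, fell from 278 ± 71.0 to 74.9 ± 20.9 CPM, a log2 fold change of -1.89 ± 0.24. MGP, the matrix Gla protein that inhibits calcification, rose from 2830 ± 1072 to 12692 ± 1869 CPM. Of 14979 genes tested with edgeR, 1699 were called, 906 higher and 793 lower in the autograft, and 4588 had an unadjusted p under 0.05. The larger side changed with FPKM + 1 (847 higher and 864 lower) and without pulmonary replicate 2 (242 and 280), pulmonary replicate 3 (222 and 283) or pulmonary replicate 4 (466 and 538). The libraries of the 2 groups did not overlap for 1572 of the 1699 called genes, and for 22.1% of all genes where chance gives 5.71%.

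The count of called genes depended on single libraries. It was 2753 without pulmonary replicate 1, 522 without pulmonary replicate 2, 505 without pulmonary replicate 3, 1004 without pulmonary replicate 4 and 452 without autograft replicate 2, and it was 2218 without both pulmonary replicate 1 and autograft replicate 1. Fitting the 2 groups alone gave 479 genes and DESeq2 gave 2997. Of the 74 called genes named for this comparison, 36 stayed called whichever single library was left out, IL2RB, MYOCD and MGP among them, 32 were lost without autograft replicate 2 and 30 without pulmonary replicate 3.

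The other genes with the largest rises were PLAC8 at 4.68 ± 0.94, the borate and proton transporter family gene SLC4A11 at 4.61 ± 0.93, the zinc transporter gene SLC39A8 at 4.32 ± 0.84, the fibrillar collagen gene COL11A1 at 4.20 ± 0.94, the interleukin-7 receptor gene IL7R at 4.17 ± 0.71, and CTSW and NKG7, both expressed in cytotoxic lymphocytes, at 4.17 ± 0.40 and 3.90 ± 0.50 (log2 fold change ± SE). The largest falls were in CPNE5 at -3.36 ± 0.55, the cell adhesion gene LSAMP at -3.27 ± 0.79, HMCN2 at -3.19 ± 0.68, the acyl-CoA synthetase gene ACSBG2 at -3.13 ± 0.58, the papilin gene PAPLN at -3.08 ± 0.38, CCDC33 at -3.08 ± 0.38, the netrin family gene NTNG2 at -2.68 ± 0.57 and the tubulin polymerization gene TPPP at -2.61 ± 0.27. PAPLN fell from 113 ± 36 to 13.4 ± 5.12 CPM. The edgeR adjusted p of these genes lay between 0.00142 and 0.0274. The call ended for PLAC8 without pulmonary replicate 3 (adjusted p = 0.0513), for SLC4A11 without pulmonary replicate 3 (0.0509) and in 1 more case, for COL11A1 without pulmonary replicate 2 (0.0633) and in 2 more cases, for HMCN2 without autograft replicate 2 (0.0581) and in 1 more case, and for LSAMP without autograft replicate 2 (0.0934) and in 4 more cases.

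Of 15 T and natural killer cell genes, 12 rose and 14 rose when adjusted over the list alone, with a median log2 fold change of 3.29. NKG7 rose, CCL5, a chemokine of T cells, rose by 4.23 ± 0.66, and CD3E, a chain of the T cell receptor complex, rose from 0.942 ± 0.662 to 7.88 ± 0.542 CPM. The mean of the list was 1.74, 1.83 and 1.85 log2 CPM in the 3 autograft libraries and between -1.49 and -0.11 in the pulmonary ones, with pulmonary replicate 1 the highest of these. This was the only list of 37 still called with an estimated correlation (camera adjusted p = 0.0358). Of 22 macrophage genes, 11 rose (21 adjusted over the list alone; median 2.06; adjusted p = 0.260 with an estimated correlation), including the lysozyme gene LYZ (2.86 ± 0.61) and LAPTM5 (1.81 ± 0.39). Both calls ended without autograft replicate 2, with adjusted p = 0.0545 and 0.0667. The call of LAPTM5 ended in 3 of the fits with a library left out. The mean of the macrophage list was 2.96 log2 CPM in autograft replicate 3 against 5.05 and 4.80 in the other autograft libraries and 3.28 in pulmonary replicate 1. Of 5 B and plasma cell genes, 3 rose (4 adjusted over the list alone; median 2.36), with BANK1 at 2.36 ± 0.40. Their adjusted p was 0.206 with an estimated correlation. Of 7 neutrophil and mast cell genes 0 passed over all genes in edgeR and 1 passed adjusted over the list alone (median 1.79; adjusted p = 0.347 with an estimated correlation). KIT stood at 1.79 ± 0.64, and the list's adjusted p was 0.0583 without autograft replicate 2, 0.0557 without pulmonary replicate 3 and 0.0621 with the random block.

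Of 26 genes of antigen presentation and interferon response, 8 rose (15 adjusted over the list alone; median 1.29; adjusted p = 0.260 with an estimated correlation), including the class I light chain gene B2M (1.09 ± 0.23) and IRF8 (1.83 ± 0.39). Of 13 complement genes, 6 rose (12 adjusted over the list alone; median 2.3; adjusted p = 0.225 with an estimated correlation), including the complement factor D gene CFD (2.99 ± 0.48). Calls that ended without autograft replicate 2 were those of B2M (adjusted p = 0.0637) and IRF8 (0.0581). Each ended in 3 of the fits with a library left out. Of 23 endothelial genes, 2 rose, the nitric oxide synthase gene NOS3 (3.03 ± 0.70) and the angiopoietin receptor gene TEK (2.41 ± 0.65), and 15 rose when adjusted over the list alone. The endothelial median was 1.85, with an adjusted p = 0.422 for the estimated correlation, and the libraries of both groups were uneven. The list mean was 2.81 log2 CPM in autograft replicate 1 against 6.28 and 5.34 in the other 2, and 4.57 in pulmonary replicate 1 against 2.77 to 2.84 in the other 3. Without autograft replicate 2 the calls of NOS3 (adjusted p = 0.0992) and TEK (0.150) ended. Over the fits with a library left out, the call of NOS3 ended in 4 and that of TEK in 7.

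Of 21 contractile smooth muscle genes, 8 fell (13 adjusted over the list alone; median -0.69; adjusted p = 0.206 with an estimated correlation). Besides MYOCD, the calls held for the phospholamban gene PLN, which fell from 2227 ± 419 to 864 ± 157 CPM (-1.37 ± 0.17), for SYNPO2 (-1.04 ± 0.16) and for the focal adhesion gene TNS1 (-1.52 ± 0.25). Of 27 calcium and potassium channel and pump genes, 11 fell and 1 rose (12 fell and 2 rose adjusted over the list alone; median -0.46; adjusted p = 0.0893 with an estimated correlation). The L-type calcium channel gene CACNA1C fell from 41.3 ± 6.45 to 15.3 ± 0.843 CPM (-1.43 ± 0.19), and the calcium pump gene ATP2A3 fell by 2.49 ± 0.34 on the log2 scale. The means of this list of 4.23, 4.31 and 4.42 log2 CPM in the autograft lay below all 8 native libraries, which spanned 4.61 to 4.79.

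**Figure D2:**
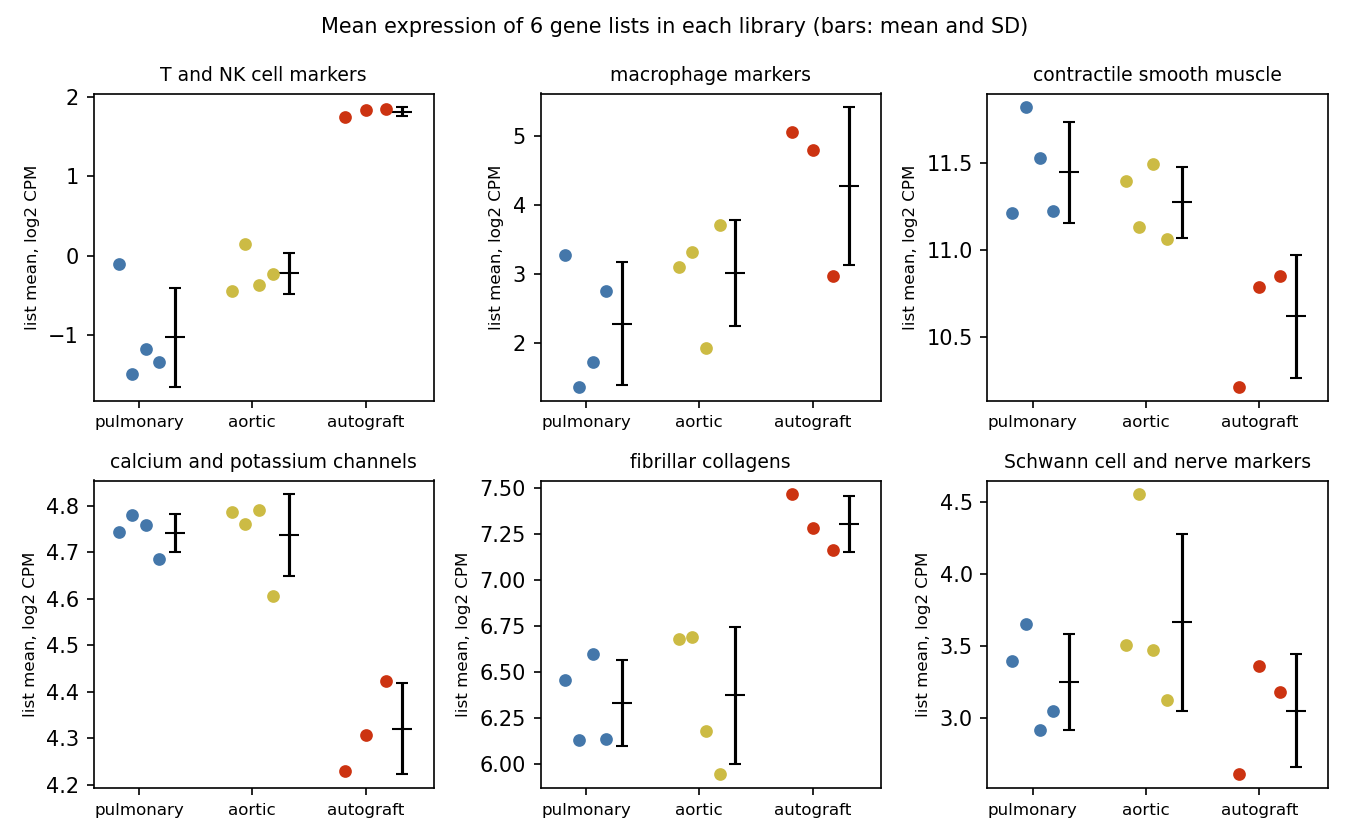
Mean log2 CPM of 6 gene lists in each library of pulmonary sinus (n = 4), aortic sinus (n = 4) and autograft sinus (n = 3); points are libraries and bars are the mean and SD. The T and NK cell list lies at 1.74 to 1.85 in the autograft and at no more than 0.15 in native tissue, and the channel list at 4.23 to 4.42 against 4.61 to 4.79.

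Of 15 genes of modulated smooth muscle, 6 rose (9 rose and 1 fell adjusted over the list alone; median 1.36; adjusted p = 0.206 with an estimated correlation), with MGP at 2.16 ± 0.34 and IGFBP2 at 3.40 ± 0.57. Of 10 fibrillar collagen genes, 4 rose (5 rose and 1 fell adjusted over the list alone; median 0.78; adjusted p = 0.206 with an estimated correlation), and with only genes of FPKM of at least 1 the list was not called (median 0.40, adjusted p = 0.0517). COL1A1 rose from 1660 ± 336 to 4435 ± 679 CPM (1.42 ± 0.21) and COL3A1 by 1.32 ± 0.30, the latter with an adjusted p = 0.0685 without pulmonary replicate 3. The call of COL3A1 ended in 4 of the fits with a library left out. Of 26 proteoglycan and matricellular genes, 5 rose (6 adjusted over the list alone; median 1.01; adjusted p = 0.260 with an estimated correlation), including the thrombospondin gene THBS1 (3.35 ± 0.59), fibromodulin gene FMOD (0.93 ± 0.16) and WISP1 (3.05 ± 0.58). Of 21 fibroblast and adventitial markers, 8 rose (10 adjusted over the list alone; median 1.03; adjusted p = 0.249 with an estimated correlation), including the Wnt modulator gene SFRP2 (3.78 ± 0.64) and the apolipoprotein gene APOD (2.0 ± 0.35). Of 18 chondrogenic and osteogenic genes, 4 rose (6 adjusted over the list alone; median 1.42; adjusted p = 0.206 with an estimated correlation). These were MGP and COL11A1, PHEX (2.83 ± 0.57) and the osteopontin gene SPP1 (3.16 ± 0.92). The call of PHEX ended without autograft replicate 2 (adjusted p = 0.0551), and that of SPP1 without pulmonary replicate 3 (0.120) and in 7 more cases.

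Of 26 matrix protease and inhibitor genes, 3 rose and 1 fell (10 rose and 1 fell adjusted over the list alone; median 0.64; adjusted p = 0.260 with an estimated correlation). The gelatinase gene MMP2 rose from 138 ± 42.7 to 584 ± 110 CPM (2.08 ± 0.26), the cathepsin K gene CTSK rose by 1.20 ± 0.27, MMP16 rose by 2.51 ± 0.63 and MMP11 fell (-1.47 ± 0.29). Of 25 collagen processing and crosslinking genes, 4 rose and 1 fell (6 rose and 2 fell adjusted over the list alone; median 0.23; adjusted p = 0.422 with an estimated correlation), with the prolyl hydroxylase subunit gene P4HA3 at 2.5 ± 0.34. Calls that ended with a library left out were CTSK without pulmonary replicate 3 (adjusted p = 0.0640), MMP16 without autograft replicate 1 (0.103) and MMP11 without autograft replicate 2 (0.0553). In that order they ended in 2, 5 and 1 of the fits with a library left out. Of 21 antioxidant genes, 6 rose and 1 fell (8 rose and 1 fell adjusted over the list alone; median 0.31; adjusted p = 0.206 with an estimated correlation), with the haem oxygenase gene HMOX1 at 1.55 ± 0.26. Of 24 genes of the unfolded protein response, 2 rose (5 adjusted over the list alone; median 0.24; adjusted p = 0.420 with an estimated correlation), DNAJB9 (0.66 ± 0.16) and XBP1 (0.49 ± 0.14). Their calls ended without pulmonary replicate 2 (adjusted p = 0.0804) and without pulmonary replicate 3 (0.132). Over the fits with a library left out, the call of DNAJB9 ended in 4 and that of XBP1 in 8. The collagen processing call also ended without autograft replicate 1 (adjusted p = 0.106). Of 28 immediate early and heat shock genes, 0 passed over all genes (edgeR) and 0 adjusted over the list alone, although the list was called with a median of 0.88 (adjusted p = 0.541 with an estimated correlation). FOS stood at 2.08 ± 0.65, and the list had an adjusted p of 0.333 without autograft replicate 3, 0.0645 without pulmonary replicate 3, 0.0546 without pulmonary replicate 4 and 0.0513 with the random block.

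The remaining 18 lists did not pass camera with all libraries (lowest adjusted p = 0.395 with an estimated correlation). fry passed 2 of them, basement membrane (adjusted p = 0.0467) and pericytes (0.0297), and did not pass 3 lists that camera called, collagen processing (0.0628), endothelium (0.129) and immediate early genes (0.175). For the elastic fibre list 0 of 19 genes passed in edgeR, also adjusted over the list alone, and its median was 0.23. In the TGF-beta and BMP list 5 of 39 genes rose and 4 fell, with a median of 0.05 and an edgeR adjusted p = 0.00142 for SKI, a repressor of that pathway's signalling, which fell from 184 ± 13.1 to 87.1 ± 7.50 CPM. In the vasoactive receptor list 5 of 32 genes rose and 5 fell, among them the prostacyclin synthase gene PTGIS (-0.97 ± 0.17). The lists of basement membrane (3 up and 6 down of 21), outflow tract regulators (5 up and 2 down of 35), mechanosensitive targets (1 up and 6 down of 25), hypoxia and glycolysis (3 up and 1 down of 25) and Wnt (2 up and 1 down of 29) had called members in both directions. So had the adipocyte list (1 up and 2 down of 14; median 2.03), whose mean was 3.77 log2 CPM in pulmonary replicate 1 against 1.60 to 1.95 in the other pulmonary libraries and which was called without autograft replicate 1 (adjusted p = 0.00194) or without pulmonary replicate 1 (0.0434). Calls also appeared without autograft replicate 2 for fatty acid oxidation (0.0340), Wnt (0.0340) and mechanosensitive lists (0.0216), without pulmonary replicate 1 for fatty acid oxidation (0.0208), Wnt (0.0337) and lymphatic lists (0.0352), without pulmonary replicate 3 for fatty acid oxidation (0.0312), and for elastic fibres without pulmonary replicate 4 (0.0403) or with FPKM (0.0168 to 0.0178). Without animal D3 they appeared for fatty acid oxidation (0.0246), lymphatic (0.0496) and Wnt lists (0.0284), and with no filter for fatty acid oxidation (0.0274). Called members numbered 2 of 21 in the cardiomyocyte list, 2 of 19 in fatty acid oxidation, 2 of 10 among pericyte markers and 1 of 15 among HOX genes, all lower. They numbered 1 of 6 among lymphatic markers and 1 of 32 in oxidative phosphorylation, both higher, and 2 of 14 in the Notch list, 1 in each direction. The lymphatic marker was the podoplanin gene PDPN at 2.46 ± 0.30. In the Schwann cell and nerve list 0 of 15 genes passed and in the cell cycle list 0 of 29, in edgeR and adjusted over the list alone. Median, mean and camera direction differed in sign for the basement membrane, cardiomyocyte, hypoxia, lymphatic, mechanosensitive, outflow tract and pericyte lists.

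**Figure D3:**
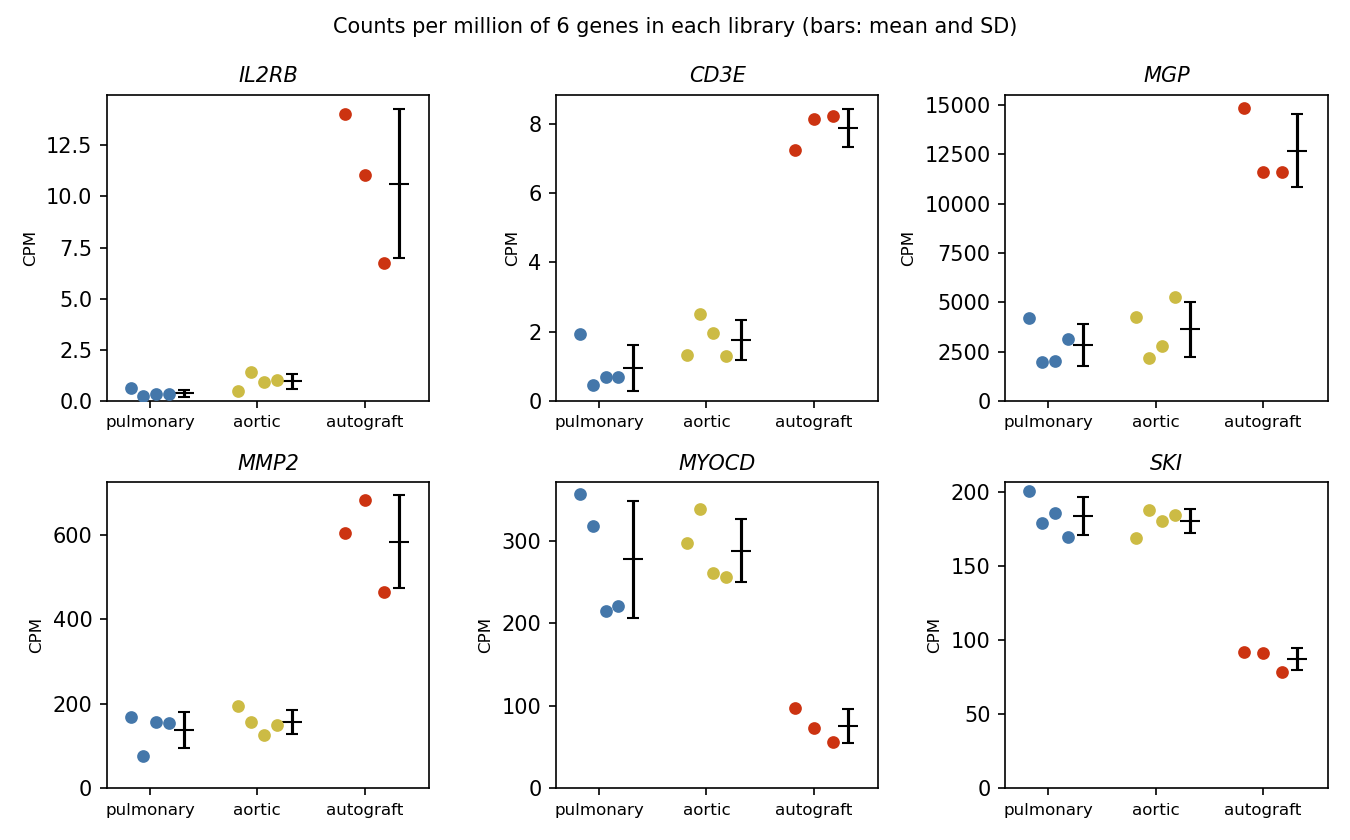
CPM of 6 genes in each library of pulmonary sinus (n = 4), aortic sinus (n = 4) and autograft sinus (n = 3); points are libraries, bars are the mean and SD, and each axis starts at 0. IL2RB, CD3E, MGP and MMP2 were higher and MYOCD and SKI lower in all 3 autograft libraries than in every native library.

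The second comparison asked how the autograft differed from the native aortic sinus. IL2RB (3.45 ± 0.41, adjusted p = 0.00516 in edgeR), CTSW (2.86 ± 0.37) and MMP2, which stood at 584 ± 110 CPM (SD, n = 3) against 156 ± 28.9 CPM (SD, n = 4), rose. MYOCD fell from 288 ± 38.4 to 74.9 ± 20.9 CPM (-1.94 ± 0.24), SKI from 180 ± 8.18 to 87.1 ± 7.50 CPM (-1.05 ± 0.10), and RFX2, a transcription factor of ciliated cells, from 144 ± 41.5 to 26.9 ± 7.85 CPM (-2.42 ± 0.28). edgeR called 356 genes, 142 higher and 214 lower in the autograft, and 3446 genes had an unadjusted p under 0.05. That balance did not hold with DESeq2 (754 higher and 715 lower), limma-voom (188 and 196) or without autograft replicate 1 (89 and 81). The libraries did not overlap for 355 of the 356, and for 20.6% of all genes where chance gives 5.71%.

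This count also rested on single libraries. It was 61, 111, 30 and 70 without aortic replicates 1 to 4 in turn, 170, 25 and 210 without autograft replicates 1 to 3, 576 without pulmonary replicate 1, 179 without pulmonary replicate 3 and 228 without pulmonary replicate 4, the pulmonary libraries entering through the shared spread. It was 110 without both D3 libraries and 400 without pulmonary replicate 1 and autograft replicate 1. DESeq2 gave 1469 genes, and the cardiomyocyte list as a covariate gave 60. Of 43 called genes followed with each library left out, 8 stayed called throughout (CCDC33, CTSW, IL2RB, MMP2, MYOCD, RFX2, SKI and TPPP). Without autograft replicate 2, 33 were lost, and likewise 33 without aortic replicate 3. PTGIR, ADRA1B, ITGA8, COL4A3 and COL4A5, named below, were not among the 43. In the fits without aortic replicates 1, 2 and 4 and autograft replicates 1 and 3, 28, 26, 27, 28 and 15 of the 43 were lost.

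The other large rises were those of PLAC8 (4.04 ± 0.90), PHEX (2.87 ± 0.56), CYTIP, expressed in leucocytes (2.72 ± 0.45), the metalloprotease gene ADAM12 (2.69 ± 0.51), THBS1 (2.68 ± 0.57) and SFRP2 (2.68 ± 0.61). The large falls were those of HMCN2 (-3.25 ± 0.68), the testosterone-forming dehydrogenase gene HSD17B3 (-2.94 ± 0.55), CCDC33 (-2.91 ± 0.38), PAPLN (-2.82 ± 0.38), ACSBG2 (-2.69 ± 0.57), CCDC13 (-2.44 ± 0.46) and TPPP (-2.34 ± 0.27). Their edgeR adjusted p lay between 0.00516 and 0.0478. The highest adjusted p with a library left out was 0.120 for PLAC8, 0.0830 for CYTIP, 0.0956 for ADAM12 and 0.118 for THBS1, each without aortic replicate 3. It was 0.105 for PHEX, 0.118 for SFRP2, 0.108 for HMCN2, 0.0851 for HSD17B3, 0.0630 for PAPLN, 0.106 for ACSBG2 and 0.105 for CCDC13, each without autograft replicate 2.

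Of the 37 lists, 16 passed camera with the preset correlation, 6 passed fry and 0 passed camera with an estimated correlation, and 12 of the 16 stayed called whichever library was left out. Of 15 T and natural killer cell genes, 6 rose (12 adjusted over the list alone; median 2.48; adjusted p = 0.0903 with an estimated correlation), including CD3E (2.15 ± 0.43), LCK (2.75 ± 0.53) and CD247 (1.36 ± 0.27). Each of these 3 had an adjusted p of at least 0.0956 without aortic replicate 3. Their calls each ended in 7 of the fits with a library left out. Of 21 contractile genes, 4 fell (8 adjusted over the list alone; median -0.58; adjusted p = 0.370 with an estimated correlation), MYOCD, PLN (-1.01 ± 0.17), SYNPO2 (-0.78 ± 0.16) and TNS1 (-1.18 ± 0.24). Of 27 channel and pump genes, 6 fell and 1 rose (11 fell and 1 rose adjusted over the list alone; median -0.39; adjusted p = 0.0903 with an estimated correlation), including CACNA1C (-1.25 ± 0.19) and ATP2A3 (-2.05 ± 0.33). Without autograft replicate 2 the calls of PLN (adjusted p = 0.0903), SYNPO2 (0.113), TNS1 (0.118), CACNA1C (0.0756) and ATP2A3 (0.0841) ended. In that order they ended in 5, 7, 8, 1 and 2 of the fits with a library left out.

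Among lists of leucocytes, 0 of 22 macrophage genes passed in edgeR (7 adjusted over the list alone; median 1.39), 0 of 13 complement genes (2; median 1.61) and 0 of 26 antigen presentation genes (0; median 0.50), and 1 of 5 B cell genes rose (2; median 1.76). In that order these lists had adjusted p = 0.406, 0.384, 0.511 and 0.370 with an estimated correlation. The list means of macrophages were 5.05, 4.80 and 2.96 log2 CPM in the autograft and 1.92 to 3.71 in aortic sinus. The antigen presentation list had an adjusted p = 0.0535 without autograft replicate 2. The endothelial list (0 of 23 genes; median 0.97; adjusted p = 0.723 with an estimated correlation) was no longer called without autograft replicate 2 (adjusted p = 0.969) or without autograft replicate 3 (0.0773). The Schwann cell and nerve list (0 of 15 genes; median -0.55; adjusted p = 0.488 with an estimated correlation) was no longer called without aortic replicate 2 (0.227). Other settings ended the calls of the endothelial list (limma-voom, 0.0684; random block, 0.117), the nerve list (FPKM of at least 1, 0.0586; cardiomyocyte covariate, 0.214) and the B cell list (cardiomyocyte covariate, 0.0503).

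Among lists of matrix and modulated cells, 3 of 15 modulated smooth muscle genes rose (7 rose and 1 fell adjusted over the list alone; median 1.13; adjusted p = 0.384 with an estimated correlation), MGP (1.81 ± 0.34), IGFBP2 (2.52 ± 0.55) and DCN (1.36 ± 0.31). In the fibrillar collagen list 1 of 10 rose, COL1A1 at 1.13 ± 0.21 (5 rose and 1 fell adjusted over the list alone; median 0.72; adjusted p = 0.312 with an estimated correlation). With only genes of FPKM of at least 1 the fibrillar collagen (median 0.42, adjusted p = 0.0846) and chondrogenic lists (0.64, 0.155) were not called. In the proteoglycan list 3 of 26 rose (6 adjusted over the list alone; median 0.73; adjusted p = 0.406 with an estimated correlation), including FMOD (0.77 ± 0.16) and THBS1. In the fibroblast list 1 of 21 rose, SFRP2 (8; median 0.84), and in the chondrogenic list 2 of 18, MGP and PHEX (3; median 0.89), each list with an adjusted p = 0.384 with an estimated correlation. In the antioxidant list 1 of 21 rose, HMOX1 at 1.14 ± 0.26 (3; median 0.21; adjusted p = 0.312 with an estimated correlation). In the protease list MMP2 (1.90 ± 0.26) rose and MMP11 (-1.23 ± 0.28) fell (3 rose and 1 fell adjusted over the list alone; median 0.46; adjusted p = 0.406 with an estimated correlation). The protease list was also lost without autograft replicate 2 (adjusted p = 0.0512). Without aortic replicate 3 the calls of MGP (adjusted p = 0.0951), IGFBP2 (0.124), DCN (0.133), COL1A1 (0.0924) and FMOD (0.0963) ended, and without autograft replicate 2 those of MMP11 (0.141) and HMOX1 (0.135). In that order they ended in 5, 8, 9, 5, 7, 8 and 10 of the fits with a library left out.

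The remaining 21 lists did not pass camera with all libraries (lowest adjusted p = 0.384 with an estimated correlation), and fry passed 1 of them, pericytes (adjusted p = 0.0480). The elastin gene ELN stood at 1896 ± 178 CPM in the autograft and 4534 ± 1856 CPM in aortic sinus without passing (-1.26 ± 0.58, adjusted p = 0.221), and 0 of 19 elastic fibre genes passed in edgeR. In the TGF-beta and BMP list SKI and PMEPA1 (-0.73 ± 0.15) fell, 2 of 39. In the vasoactive list 3 of 32 genes fell, including the prostacyclin receptor gene PTGIR (-1.54 ± 0.28) and the adrenergic receptor gene ADRA1B (-1.44 ± 0.29). HOXA3 (-1.20 ± 0.26) fell in the HOX list, FOXC2 (-0.97 ± 0.17) in the outflow tract list and ITGA8 (-0.55 ± 0.11) in the mechanosensitive list, and PDPN (1.97 ± 0.30) rose in the lymphatic list. Basement membrane genes (COL4A3 at 1.69 ± 0.29 and COL4A5 at -1.03 ± 0.22), collagen processing genes (P4HA3 at 1.81 ± 0.33 and LOXL3 at -0.60 ± 0.14) and the Wnt list had 1 rise and 1 fall each. The calls of PMEPA1 (edgeR adjusted p = 0.102), HOXA3 (0.124) and FOXC2 (0.0931) ended without autograft replicate 2. Those of P4HA3 (0.0924), LOXL3 (0.130) and PDPN (0.0503) ended without aortic replicate 3. In that order they ended in 8, 8, 6, 6, 9 and 1 of the fits with a library left out. For the adipocyte, cardiomyocyte, cell cycle, fatty acid oxidation, hypoxia, immediate early, neutrophil, Notch, oxidative phosphorylation, pericyte and unfolded protein lists 0 genes passed. Calls appeared without autograft replicate 1 for adipocyte (adjusted p = 0.0311) and immediate early lists (0.00494), without autograft replicate 2 for HOX (0.0376), cardiomyocyte (0.0178) and mechanosensitive lists (0.00530), and without autograft replicate 3 for collagen processing (0.0133) and neutrophil lists (0.0494). They appeared without aortic replicate 1 for HOX (0.00879) and mechanosensitive lists (0.0248), without aortic replicate 2 for immediate early genes (0.0256), without aortic replicate 3 for cardiomyocyte (0.0348) and unfolded protein lists (0.0411), and without aortic replicate 4 for the same 2 (0.0120 and 0.0299). Other settings added calls of cardiomyocyte (0.0293), mechanosensitive (0.0222) and neutrophil lists (0.0126) with no filter, of collagen processing (0.0152) and neutrophil lists (0.0143) with FPKM + 1, of HOX (0.00695) and mechanosensitive lists (0.0230) without animal D3, and of immediate early genes with the cardiomyocyte covariate (0.00412). Median, mean and camera direction differed in sign for the basement membrane, hypoxia, Notch, oxidative phosphorylation, pericyte, TGF-beta and vasoactive lists.

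The third comparison, aortic against pulmonary sinus, gave no called gene. The Wnt inhibitor gene WIF1 stood at 121 ± 47.9 CPM in aortic and 37.3 ± 24.2 CPM in pulmonary sinus (SD, n = 4 each; log2 difference 1.70 ± 0.45) with an edgeR adjusted p of 0.999953. The interferon-inducible NLRC5 (0.96 ± 0.26), the cardiac myosin-binding protein gene MYBPC3 (3.73 ± 1.14) and the cardiac transcription factor gene NKX2-5 (-3.01 ± 1.04) did not pass either. edgeR called 0 of 14979 genes with 306 at an unadjusted p under 0.05, DESeq2 called 0 with 391 and limma-voom 0 with 330. The libraries did not overlap for 1.42% of all genes, where chance gives 2.86%. Without pulmonary replicate 1 the count stayed 0, with 1241 genes at an unadjusted p under 0.05, and in a fit of only the 2 native groups it stayed 0, with 365 without a block and 598 with a block by animal.

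Of 37 lists 25 were nonetheless called by camera with the preset correlation, although 0 of their genes passed over all genes or adjusted over the list alone. With an estimated correlation 0 lists passed (lowest adjusted p = 0.379), fry called 0 (lowest adjusted p = 0.523), and 7 of the 25 stayed called whichever library was left out. These 7, all higher in aortic sinus, were T and natural killer cells (median 1.16; NKG7 at 1.32 ± 0.47), antigen presentation and interferon (0.62; ISG15 at 1.15 ± 0.37), endothelium (0.90; KDR at 0.66 ± 0.39), macrophages (0.61; LAPTM5 at 0.63 ± 0.37), complement (0.64; CFD at 1.29 ± 0.45), lymphatic vessels (0.57; LYVE1 at 0.86 ± 0.62) and the unfolded protein response (0.15; MANF at 0.43 ± 0.15). Pulmonary replicate 1 lay on the aortic side of these lists. Its T and natural killer cell mean was -0.11 log2 CPM against -1.49 to -1.18 in the other pulmonary libraries, and its endothelial mean 4.57 against 2.77 to 2.84.

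The 18 lists that lost the call without some library, none with an adjusted p under 0.379 with an estimated correlation, included adipocytes (median 1.05), B cells (0.53; CD22 at 1.70 ± 0.71), modulated smooth muscle (0.38), neutrophils and mast cells (0.59), Schwann cells and nerve (0.23; MBP at 1.48 ± 0.50), fibroblasts (0.24; APOD at 0.98 ± 0.33), proteoglycans (0.15), immediate early genes (0.29), collagen processing (0.14), chondrogenic genes (0.38; SPP1 at 2.03 ± 0.86), Wnt (0.12), vasoactive receptors (0.20), proteases (0.28) and elastic fibres (0.13), all on the aortic side. On the pulmonary side lay contractile genes (-0.15; PLN at -0.36 ± 0.15), oxidative phosphorylation (-0.06) and fatty acid oxidation (-0.06). The adipocyte list had an adjusted p = 0.131 without aortic replicate 2. The cardiomyocyte list had a median of 0.72, with aortic means of 2.79, 3.71, 2.24 and 1.95 log2 CPM, and in a fit of only the 2 native groups its median was 0.45 (adjusted p = 0.0371) without a block and 0.41 (0.0581) with a block by animal. The channel list, not called in that fit without a block (adjusted p = 0.0589), was called with the block as labelled (median -0.06, 0.0184) but not with D3 and D4 crossed (-0.07, 0.0704). Among the lists not called with all libraries, calls appeared without aortic replicate 1 for channels (0.0489), antioxidant (0.0430), cell cycle (0.000571), HOX (0.00270) and TGF-beta (0.0469) lists. Without aortic replicate 3 they appeared for channels (0.0369), antioxidant (0.00905) and cell cycle (0.0226) lists, without pulmonary replicate 1 for cell cycle (0.0244) and TGF-beta (0.0222) lists, and without pulmonary replicate 4 for channels (0.0314). Limma-voom ended the calls of adipocyte (0.0585), B cell (0.0539), cardiomyocyte (0.118), fatty acid oxidation (0.0539), protease (0.0821) and vasoactive lists (0.0792), and the random block ended the same 6. FPKM + 1 ended those of B cell (0.295), contractile (0.0654), neutrophil (0.0873) and Wnt lists (0.0582). The cardiomyocyte covariate ended those of adipocyte (0.890), immediate early (0.845) and protease lists (0.454). The antioxidant list gained a call with FPKM + 1 (0.0196) or that covariate (0.0349). The number of called lists was 11 without pulmonary replicate 2, 15 without aortic replicate 2 and 28 without aortic replicate 1. In the 12 lists not called, median, mean and direction differed in sign for the mechanosensitive list.

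Genes called against both native sinuses separate the operated animals' autografts from the native tissue of other animals, so tissue, surgery and animals are not told apart. edgeR called 341 genes in 1 direction against both, among them IL2RB, CTSW, NKG7, MGP and MMP2 (higher) and MYOCD, PLN, CACNA1C, SKI, PAPLN and TPPP (lower). In 20 simulations the 3 autograft libraries were drawn at the mean of the native libraries. The median and the highest number were 0, and independent lists would share 19.9. Each gene was drawn on its own, without the correlation between genes of real libraries, so the 0 is not a full baseline for 341. The 3 autograft libraries enter both comparisons and are too few to be halved, so part of the excess may come from the shared libraries. Of 100 choices of 3 libraries as the autograft group, 1 gave as many genes, the real one, and the highest of the others gave 1. The number was 60, 106, 30 and 70 without aortic replicates 1 to 4, 168, 25 and 209 without autograft replicates 1 to 3, 535 without pulmonary replicate 1, 163 without pulmonary replicate 3 and 216 without pulmonary replicate 4. DESeq2 gave 1329. Genes called in autograft against pulmonary and in aortic against pulmonary sinus numbered 0, because aortic against pulmonary sinus gave 0 calls in edgeR. Simulations, independent lists and 6 halvings of the pulmonary libraries gave 0 as well.

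The position of the autograft between the native sinuses could not be read. Its mean score was 4.0 ± 1.79 (SD, n = 3) on a scale with pulmonary sinus at 0 and aortic sinus at 1, with an exact permutation p = 0.2 against pulmonary and 0.0286 against aortic sinus. In native animals held out of the gene choice the gap between the sinuses ran from -0.130 to 0.338 and was not above 0 in 2 of 6 choices. Pulmonary replicate 1 scored 6.76, beyond the aortic end. With 200 genes the mean was 3.78, with an exact p = 0.0857 against aortic sinus, with a set larger than 500 genes it was 6.65, with FPKM + 1 it was 7.43, and without single autograft libraries it ran from 3.0 to 4.71. Over the 6 choices of native animals it ran from -1.51 to 12.6.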

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

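Of the tests below, those chosen only after the result was seen were the comparison of the T cell list with the nerve list, the test with the authors' FPKM, the D3 and D4 test on genes with a gap above 3, the fit without pulmonary replicate 1 for the native comparison, the test of that library for an outside animal, and the regrouping of genes shared by autograft and aortic sinus. In 272 measures over the native groups of 4 libraries, 16 had 1 library far from the other 3 by Dixon's criterion. Chance flags about 1 in 20 groups, 13.6 of 272 here, so the number as a whole is near chance, but 5 of the 16 fell on pulmonary replicate 1. In that library the list means were 3.77 log2 CPM for adipocytes (other pulmonary libraries 1.60 to 1.95), 4.57 for endothelium (2.77 to 2.84) and 6.22 for pericytes (5.80 to 5.82), PECAM1 stood at 6.82 (4.92 to 4.94), and SLC4A11 at -0.35 (-2.30 to -2.16). In aortic replicate 2 the hypoxia list stood at 5.21 (4.88 to 4.94) and the Notch list at 5.46 (4.82 to 4.90), and in aortic replicate 4 the calcium and potassium channel list stood at 4.61 (4.76 to 4.79). Among single genes far from their group were CPNE5 in pulmonary replicate 3 at 3.66 (1.70 to 2.02), FOXC2 in pulmonary replicate 4 at 5.45 (6.14 to 6.17) and LSAMP in the same library at 0.82 (3.42 to 3.89). In pulmonary replicate 2 JCHAIN stood at 2.10 (2.75 to 2.88), LYZ at -2.59 (-0.56 to -0.14) and MMP2 at 6.22 (7.26 to 7.38). MMP16 in aortic replicate 1 stood at 5.23 (3.75 to 3.88), and PCOLCE in aortic replicate 3 at 7.98 (8.63 to 8.73).

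Regrouping the libraries at random tests whether the counts of calls need the real groups. For autograft against aortic sinus 1 of 35 groupings, the real one, reached 356 genes, and the next gave 2. For autograft against pulmonary sinus 2 of 35 reached 1699 genes. The other one, with 1927 genes, set pulmonary replicates 2 to 4 against the autograft together with pulmonary replicate 1, and the next gave 68. Chance is thus not excluded for that count at 0.05, and the larger count belongs to a grouping that moves pulmonary replicate 1 to the autograft. For called lists 6 of 35 groupings reached 19 (highest other 22) for autograft against pulmonary, and 8 of 35 reached 16 (highest other 18) for autograft against aortic sinus, so the numbers of called lists do not exceed chance. For aortic against pulmonary sinus all 35 reached 0 genes (highest other 6) and 1 of 35 reached 25 lists (highest other 20). The native libraries are paired by animal, and only 8 of the 35 splits part all 4 pairs, too few for a share under 0.05. Among these, with the pairs as labelled, the real split gave 0 genes and 25 lists and the highest other 2 genes and 20 lists. The remaining splits set libraries of 1 animal on the same side. With D3 and D4 crossed, the highest other counts among splits that part all pairs were 0 genes and 18 lists. Of 100 choices 1, the real one, reached 341 genes called against both native sinuses (highest other 1), and all 35 reached 0 genes shared by autograft and aortic sinus against pulmonary sinus (highest other 2).

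The first pattern weighed is the rise of leucocyte lists with the fall of the contractile list in the autograft against pulmonary sinus, seen in T and natural killer cell genes such as IL2RB and contractile genes such as MYOCD (adjusted p = 0.206 to 0.347 with an estimated correlation, and 0.0358 for the T and natural killer cell list). A lower share of smooth muscle would raise the lists of all other cell types alike only if smooth muscle expressed none of their genes. The T and natural killer cell list rose by 3.03 ± 0.39 log2 units (SE) more than the nerve list, where the bound was 0.784. It rose by 1.65 ± 0.26 more than the fibroblast list. The gaps to macrophages (0.84 ± 0.74), endothelium (1.28 ± 1.02) and adipocytes (1.47 ± 0.90) were not apart from 0. An equal rise of all these lists is thus excluded. Smooth muscle expression of the nerve and fibroblast genes was not measured, so a lower share of smooth muscle is not excluded. A dilution of smooth muscle RNA by 1 factor would lower all contractile genes alike only if no other cell type expressed them. Relative to their list's mean 4 of 21 contractile genes changed (limma), with MYOCD at -1.06, PLN at -0.53, MYH11 at -0.51 and TPM1 at 0.57. A fall of all 21 by 1 factor is thus excluded. Which cell types expressed each gene was not measured, so a dilution of smooth muscle RNA is not excluded. With the authors' FPKM, whose distribution was made equal between libraries, the contractile and the T and natural killer cell list stayed called (larger camera adjusted p = 0.000177). The contractile list has an adjusted p = 0.206 with an estimated correlation on counts. Both lists thus kept their direction under this correction. The FPKM calls rest on the preset correlation, and an estimated one was not run with FPKM. A composition difference is therefore not excluded as the whole cause. The medians were -0.67 and 0.98 with FPKM and -0.69 and 3.29 on counts. These sizes are not comparable, because 1 was added to each FPKM before the log2. Entry of lymphocytes together with lower transcription of some contractile genes in the operated tissue remains open, and sinus tissue with a sham operation or from an earlier time was not compared.

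The second pattern weighed is that the aortic libraries of animals D3 and D4 resembled the pulmonary library of the other animal. The test used 44 genes outside the fixed lists with a gap of 2 to 3 log2 units. These on-off genes were on in some native libraries and off in others. The crossed pairs agreed in 85.2% of cases (75 of 88) and the labelled pairs in 44.3% (39 of 88, upper bound 55.3%). D5 and D6 as labelled agreed in 72.7% of cases. Crossed animal labels in 1 tissue fit. The bounds count each gene in each pair as independent, although genes of a library can vary together. The correlations that showed the pattern came from the same libraries, so the on-off genes are not independent evidence. Genes of the fixed cell type lists, such as those of fat, are excluded as the only cause. The 27 genes with a gap above 3 outside those lists gave 87.0% for the crossed pairs (47 of 54). The labelled pairs gave 42.6% (23 of 54, upper bound 56.8%). Cell type genes outside the lists were not removed, so shared cell content is not excluded. TYRP1, for example, differed within D6, with 160 counts in the aortic and 0 in the pulmonary library. Fits with all libraries and no block do not use the animal names, but the counts without animal D3 and the position score do.

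The third pattern weighed is the absence of called genes between aortic and pulmonary sinus, where WIF1 (1.70 ± 0.45) and NLRC5 (0.96 ± 0.26) had differences that did not pass. Pulmonary replicate 1 correlated better with the aortic libraries (mean r = 0.973) than with the other pulmonary ones (0.954), so it could hide a difference. By smaller margins the same held for pulmonary replicate 4 (0.9662 and 0.9657). Aortic replicate 3 correlated better with the pulmonary libraries (0.9718) than with the other aortic ones (0.9675). The fits without pulmonary replicate 1 were the ones examined here. Without pulmonary replicate 1 edgeR still called 0 genes, but genes at an unadjusted p under 0.05 rose from 306, where chance gives 749, to 1241. Without any other single library they numbered 157 to 392. Whether pulmonary replicate 1 hides a difference stays open. Pulmonary replicate 1 had the on or off state of aortic replicate 2 for 91.5% of 71 on-off genes (lower bound 82.5%). It had that of another aortic library for at most 54.9% (upper bound 66.8%, with genes counted as independent in both bounds). These 2 libraries were also the highest of their groups in the adipocyte (3.77 and 4.37 log2 CPM) and endothelial (4.57 and 5.15) list means. Shared cell content could give the same agreement, so an animal from outside this series is not excluded for pulmonary replicate 1. Tissue taken nearer to the vessel's outer layer and a small true difference stay open too, untested.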

How the results depend on the processing

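Under the alternatives, 0 of 2117 values of 79 gene results in autograft against pulmonary sinus reversed (1780 the same, 314 weaker, 23 stronger). In autograft against aortic sinus 0 of 1473 reversed (1052, 398 and 23), and all 242 in the native comparison stayed the same. A sign change counted as reversed only where the gene was called in either fit. With 0 native calls in every setting, the 242 could only stay the same. The genes were named for large or low-p differences in these same data, so reversals were unlikely. Genes called in autograft against pulmonary sinus, in autograft against aortic sinus and against both numbered 1699, 356 and 341 in the edgeR fit. They numbered 2997, 1469 and 1329 with DESeq2, which shared 1692 of the 1699 and all 356. With only the 2 groups compared they numbered 479, 257 and 169. Those of the calls with a log2 fold change of at least 1 numbered 877, 201 and 182, with the cardiomyocyte covariate 1517, 60 and 59, and without animal D3 2362, 110 and 103. Leaving out single libraries gave 452 to 2753, 25 to 576 and 25 to 535. DESeq2's size factors (1717, 338 and 326), total counts (1665, 369 and 353), no filter (1548, 289 and 282), limma-voom (1632, 384 and 372), run 1 (1275, 257 and 244), run 2 (1516, 323 and 311) and FPKM + 1 (1711, 369 and 359) stayed within 1.5 times. The genes were not all the same. DESeq2's size factors shared 1667 of the 1699 and 328 of the 356, run 1 shared 1122 and 209, and FPKM + 1 shared 1255 and 215. Without pulmonary replicate 1 and autograft replicate 1, chosen after the data were seen, they numbered 2218, 400 and 375. Where no reason is given the cause was not tested.

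The replicate number as a block, fitted on only the 2 groups compared and so set beside 479, 257 and 169, gave 0, 79 and 0, with 3878 genes against pulmonary and 2950 against aortic sinus at an unadjusted p under 0.05 (3819 and 3329 without the block; edgeR). Autograft libraries correlated with aortic libraries of the same number by 0.03, 0.22 and 0.13 and with pulmonary ones by 0.06, -0.01 and 0.14, so they share only a number. The random effect was the animal instead, in limma-voom with all 3 groups. It gave 1611, 361 and 349 (correlation 0.121), against 1632, 384 and 372 in limma-voom without a block. In the native comparison every setting gave 0 genes, also a block with D3 and D4 crossed, with 1173 at p under 0.05. Beyond the lists named with it, the animal block changed no call of a gene.

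Lists called numbered 19, 16 and 25 in the 3 comparisons, 1, 0 and 0 with an estimated correlation, and 18, 6 and 0 with fry. Single libraries left out gave 18 to 23, 16 to 18 and 11 to 28. With the number as a block the elastic fibre list against pulmonary sinus was called (adjusted p = 0.00888) and the immediate early list was not (0.0518), and against aortic sinus the cardiomyocyte (0.0121), collagen processing (0.0220) and neutrophil (0.0464) lists were called (camera). The camera direction reversed in the native comparison, without passing, for the cardiomyocyte list (median still above 0 at 0.0558, adjusted p = 0.890) and the nerve list (-0.217, 0.949) with the cardiomyocyte covariate, and for oxidative phosphorylation without pulmonary replicate 2 (0.000939, 0.936; -0.116 to 0.000939 with each library left out). Medians of called lists that changed sign with no reversed direction were those of fatty acid oxidation without pulmonary replicate 2 (0.00719), immediate early genes with the covariate (-0.0742) or without aortic replicate 2 (-0.0104), and nerve without aortic replicate 2 (-0.115). The position of 4.0 was 3.78 with 200 genes (exact p = 0.0857), 6.65 with a set larger than 500 genes, 7.43 with FPKM + 1 and 3.0 to 4.71 with single autograft libraries left out, where fewer samples raise the smallest possible p. At this depth 2-fold changes were recovered in 52.2%, 46.3% and 64.2% of simulated genes, all with a native mean above 5 CPM. A gene that did not pass is thus not shown to be unchanged.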

Other observations

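The sums of receptor segment genes and the pigment cell genes below were chosen only after the data were seen, and the list of motile cilium genes was written after the largest falls were seen but before it was tested. Antigen receptor segment genes, whose transcripts come from B and T cells, were summed per library. Of 209 such genes in RefSeq, 40 were among the counted symbols, and 7 were tested, of which 5 were called higher against pulmonary and 4 against aortic sinus (edgeR), with 0 lower. Their sum was 26.3, 1786 and 139 CPM in autograft replicates 1 to 3, 6.38 to 9.52 CPM in aortic and 3.30 to 6.82 CPM in pulmonary sinus. The log2 difference was 5.28 against pulmonary and 4.53 against aortic sinus, with an exact permutation p = 0.0286 for each, the smallest possible with 3 against 4 libraries.

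Genes of pigment cells were present in few libraries, in all 3 groups. TYRP1, an enzyme gene of melanin synthesis, stood at 8.59 CPM in aortic replicate 4 (160 counts), 5.25 CPM in pulmonary replicate 1 (93 counts) and 1.80 CPM in autograft replicate 2 (31 counts), with 0 counts in the other libraries. DCT stood at 2.74, 2.26 and 0.699 CPM in these libraries and at 1 count in autograft replicate 1, and MLANA at 2.90, 2.03 and 1.22 CPM. PMEL stood at 7.36, 6.61 and 7.34 CPM there and at 1.03 to 2.85 CPM in the others.

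RFX2 and the coiled-coil genes CCDC33 and CCDC13 were among the largest falls in the autograft, and RFX2 acts in ciliated cells. The hypothesis that a motile cilium programme is lower as a set was tested on other motile cilium genes. Of 78 such genes 36 were tested, with medians of -0.06 against pulmonary and 0.02 against aortic sinus, 0 higher and 1 lower against pulmonary sinus, and a larger camera p of 0.856. A lower set was thus not seen among the 36 genes tested, although a small shift is not excluded. The test does not decide the matter for the rest of the 78 genes, which were not tested.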
